A study of Mizuhopecten yessoensis with 6 samples.

How the data were processed

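RNA was measured in gill of the Yesso scallop (Mizuhopecten yessoensis), a cold-water bivalve, after 24 h in water at a dissolved oxygen level of 9 mg/L (normal, 3 libraries) or 1 mg/L (hypoxia, 3 libraries). Each library came from 1 scallop picked at random from its treatment group, per the series' design text. The number of tanks is not given in the sources used here, so the p-values measure the spread between scallops and do not separate a tank from its oxygen level. RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V5 kit, per the labels' protocols. The metabolite measurements named in the study's title were not analysed here.

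The authors deposited 1 table of FPKM values (fragments scaled to gene length and library total) with 20815 genes and 1 column per library. The submitters' processing notes name fastp, HISAT2 and HTSeq. Their versions and settings, the genome build and the annotation are not given in the sources used here. Whether reads were counted by strand, and how reads that fit several genes were treated, is likewise not given. Every column was matched to its sample by the name in the sample's title, and 0 columns were left unmapped. The FPKM values were used as deposited, with no further scaling in the main test.

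The deposited FPKM values were also turned back into whole reads. For the 11 mitochondrial genes, a whole-number library total was sought that makes every count whole at the gene's length in the reference table. Whole-number lengths between 50 and 60000 bases were then sought for the other genes, with a tolerance of 0.002 reads. A length was found for all but 2 genes. Of 500 control genes, 100% came out whole with the totals found and 0% with totals altered in steps of 0.1%. On simulated data with 289 genes, all 6 totals and 97.6% of the lengths were recovered. The library totals were 25930694, 25380901 and 24062577 reads for normal replicates 1, 2 and 3, and 26695289, 27900042 and 27486043 for hypoxia replicates 1, 2 and 3. An average of 99.7% of each total lay on listed genes. The totals are those by which FPKM was scaled and need not equal the number of reads sequenced. Read counts and shares of reads below come from this recovery. PCR copies are not independent molecules, so a floor of 3 reads covers counting error only.

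Gene names were sought in a RefSeq gene table of assembly ASM211388v2, in which all 20815 identifiers were found. For nuclear genes that table gives the same LOC identifier and no description, and only the 11 mitochondrial genes have a gene symbol. The names of the nuclear genes were therefore not used here. Of 34 gene lists written before the data were examined, 1 could be tested (the mitochondrially encoded genes). The oxidative phosphorylation list matched only COX1 and COX3 among its members, and 32 lists had no matched member. The planned test of product families was not run for the same reason. The table was used only for names and for which genes neighbour each other. Scaffold ends were placed where positions start again in table order, and genes were called adjacent when no other tested gene lay between them.

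Genes at FPKM of 1 or more in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3. The model was limma-trend on log2(FPKM + 1), two-sided, with group as the only term and Benjamini-Hochberg adjustment over all tested genes. The threshold was an adjusted p of 0.05. Log2 changes are hypoxia minus normal on the log2(FPKM + 1) scale, which understates the change of low genes. The mitochondrial list was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Values per library were compared with exact two-sided permutation tests, for which the smallest possible p is 0.1 with 3 against 3. In a simulation, residual SDs from these libraries were shuffled over the genes, and 200 of 13744 genes were changed by known amounts. The limma test recovered 87% of those changed 4-fold and 39% of those changed 2-fold, with 10 false calls. Shuffling removes the link between a gene's level and its spread, so these rates need not hold for the real data.

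The rule for named genes was also fixed before the data were examined. Since identifiers could not be paired with names, it takes the 2 identifiers with the largest increase and the 2 with the largest decrease, plus the mitochondrial list. A run of 5 neighbouring genes was singled out after its values were seen. Alternatives covered the pseudocount (0.1), filters on low values, library scaling, quantile normalization, the variance model, library weights, the replicate number as a block, and each library left out in turn. Limma's voom on the recovered reads and the removal of each library's trend with transcript length (loess, span 0.5) were added after the data were seen. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and statmod 1.5.0.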

Results

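The study asked how scallop gill responds to low oxygen. Gill is the organ of gas exchange in bivalves and is in direct contact with the surrounding water. Transcripts were profiled in 3 scallops held at normal oxygen (9 mg/L) and 3 held under hypoxia (1 mg/L) for 24 h. Library totals recovered from the FPKM values ran from 24062577 to 27900042 reads. Expression was given as FPKM for 20815 genes, of which 13744 passed the filter on low values (13733 nuclear and 11 mitochondrial).

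Hypoxia was accompanied by more rises than falls in gill transcripts. By limma with Benjamini-Hochberg adjustment, 203 genes rose and 59 fell, together 1.91% of the genes tested, and 77.5% of the changed genes rose. The genes that rose went from a median of 5.20 FPKM in normal scallops to 18.3 FPKM under hypoxia, with a median log2 change of 1.42 and a range from 0.68 to 5.71. Those that fell went from a median of 16.1 to 5.65 FPKM, with a median log2 change of -1.23 and a range from -4.29 to -0.62. At 10-fold or more in mean FPKM, 29 genes rose and 9 fell. The counts of changed genes depend on the settings, with 99 higher and 27 lower without a filter on low values. With the replicate number as a block they were 46 and 5. The block adds terms to the fit of only 6 libraries, which can lower the number of calls by itself.

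Genes nearly silent at normal oxygen made up part of the rise. Of the 203 genes, 31 started from a normal mean below 1 FPKM, and 1 of them had 0 reads in every normal library. At the other end, 24 of the genes that rose reached 100 FPKM or more under hypoxia. Of the 59 genes that fell, 15 ended below 1 FPKM and 6 had 0 reads in every hypoxia library. A gene with a mean below 1 FPKM in 1 group passes the filter only with help from the other group. Such rises and falls are thus partly built in, and how common such genes are among all tested genes is not given here. The genes that rose held 0.828 ± 0.136% of all reads in normal gill and 3.33 ± 0.063% under hypoxia (SD, n = 3 each). The genes that fell held 0.555 ± 0.017% and 0.252 ± 0.00048%. These shares describe genes chosen on the same libraries and are not a separate test.

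**Figure D1:**
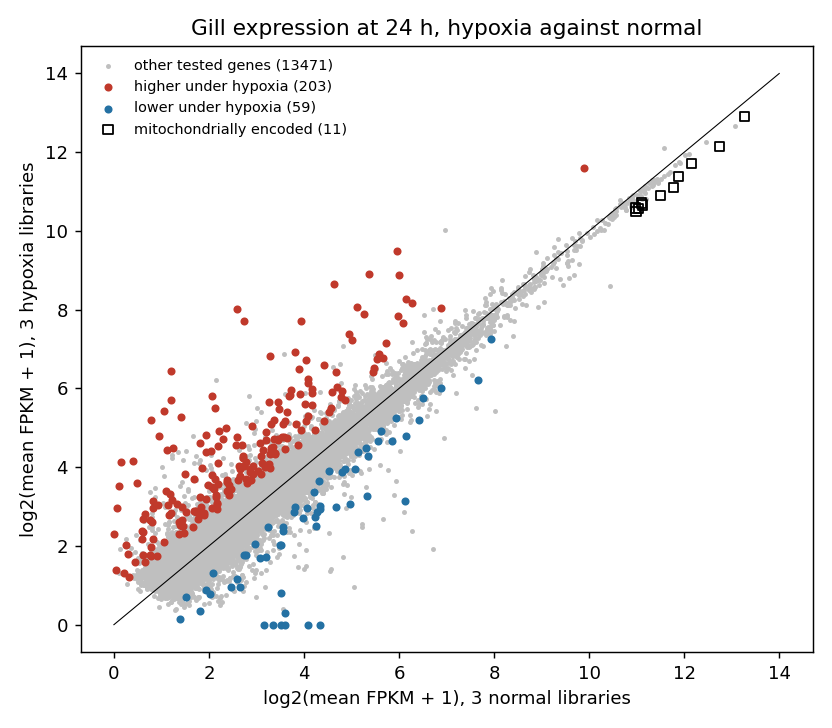
Mean expression of 13744 genes in gill, as log2(mean FPKM + 1) over 3 normal libraries (x axis) and 3 hypoxia libraries (y axis), with the line of equality. Red points are the 203 genes that rose, blue points the 59 that fell, 6 of them at 0 under hypoxia, and open squares the 11 mitochondrially encoded genes, which lie below the line on the deposited scale (COX1 turned to +0.15 under quantile normalization) with 0 past the threshold.

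The named genes were ranked by their change in log2(FPKM + 1). LOC110461223 rose from 5.03 ± 4.75 FPKM in normal gill to 258 ± 50.6 FPKM under hypoxia (SD, n = 3 each). Its log2 change was 5.71 (SE 0.55, limma adjusted p = 0.0080). LOC110446317 rose from 1.31 ± 0.25 to 86.0 ± 7.84 FPKM, with a log2 change of 5.24 (SE 0.14, limma adjusted p = 0.00013). The order of these 2 genes depends on the measure. It held with a pseudocount of 0.1 (log2 changes of 6.09 and 5.94) and with voom on the recovered reads (6.14 and 6.05). It turned in the ratio of mean FPKM, which was 51.3 for LOC110461223 and 65.7 for LOC110446317, and without normal replicate 2 (log2 changes of 5.18 and 5.32). Among the falls, LOC110466915 had 19.1 ± 5.59 FPKM in normal gill, from 1415, 2502 and 1757 reads, and 0 reads in each hypoxia library. It was at least 670.8-fold lower under hypoxia, taking a floor of 3 reads per library (limma adjusted p = 0.00093). LOC110458710 had 16.1 ± 8.43 FPKM in normal gill, from 371, 471 and 131 reads, and 0 reads in each hypoxia library. It was at least 113.6-fold lower on the same floor (limma adjusted p = 0.011). The sources used here give no protein name for any of these 4 genes.

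Genes that rose also lay next to one another. The longest run held 5 neighbouring genes, and it was singled out after its values were seen. LOC110447376 went from 5.69 ± 1.92 to 207 ± 52.5 FPKM, a log2 change of 4.97. LOC110447322 went from 14.2 ± 1.52 to 209 ± 42.3 FPKM, a log2 change of 3.77. LOC110447383 went from 1.29 ± 0.58 to 50.9 ± 8.98 FPKM, and LOC110447397 from 0.729 ± 0.408 to 35.8 ± 5.20 FPKM, log2 changes of 4.52 and 4.43. The smallest of the 5 rises was that of LOC110447345, from 29.7 ± 10.9 to 166 ± 16.98 FPKM, a log2 change of 2.51. Its limma adjusted p, 0.013, was the highest of the 5.

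**Figure D2:**
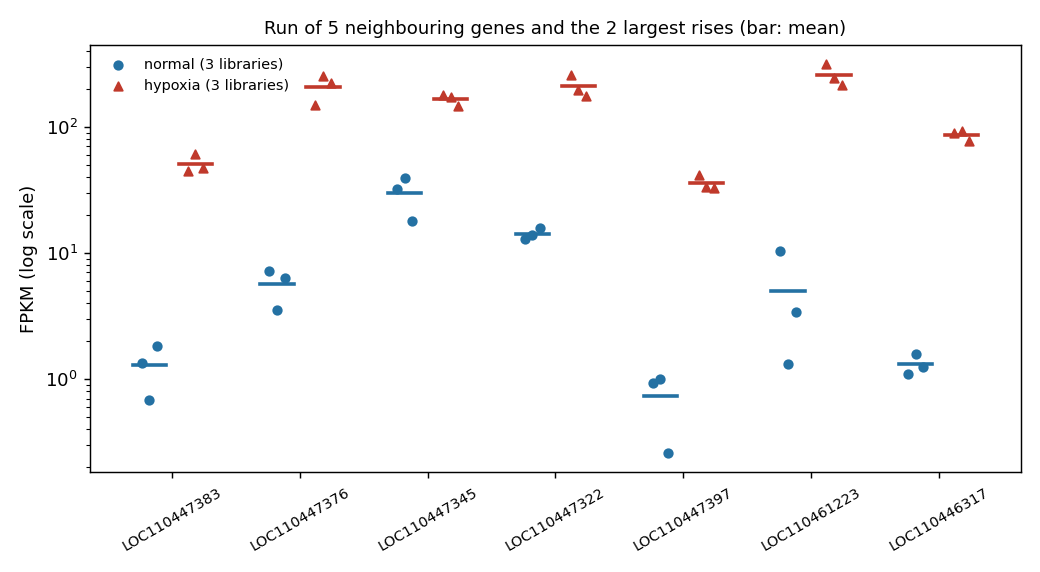
FPKM per library on a log scale for the run of 5 neighbouring genes (left) and the 2 genes with the largest rise in log2(FPKM + 1) (right). Circles are the 3 normal and triangles the 3 hypoxia libraries, and bars are means. In each of these genes every hypoxia library lies above every normal library, as in LOC110461223, where the means are 5.03 and 258 FPKM.

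The groups did not overlap in any of the 262 changed genes, nor in 25.9% of all tested genes, where chance gives 10%. The changed genes were chosen on the same libraries, so their separation is not a separate test. Genes also vary together, so a share above 10% can arise by chance, and the share in other splits is not given here. The first principal component held 35.2% of the variance and separated the groups. Across genes, correlations between libraries were 0.928 to 0.940 within normal, 0.941 to 0.951 within hypoxia and 0.910 to 0.927 between the groups. The number of calls depended on single libraries. It was 172 higher and 43 lower without normal replicate 1, 105 and 11 without normal replicate 2, and 72 and 13 without normal replicate 3. Of these, 124 and 21, 87 and 10, and 67 and 10 were also called in the main test. Without hypoxia replicate 1, 2 or 3 the number of calls was 45 and 9, 38 and 8, or 42 and 13. Of those, 44 and 8, 36 and 7, and 41 and 7 were also called in the main test. Fewer libraries enter these fits, which lowers the number of calls by itself. The filter also kept only 47 of the 59 falls without a normal library, and 177 of the 203 rises without a hypoxia library. LOC110461223 missed the threshold only without hypoxia replicate 2 (limma adjusted p = 0.051), while LOC110447345 and LOC110458710 missed it without any 1 of the hypoxia libraries (0.054 to 0.077).

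Transcripts encoded by the mitochondrial genome had lower mean values under hypoxia in all 11 genes, except that COX1 turned to +0.15 under quantile normalization, and 0 of the 11 passed the limma test over all genes. These genes encode subunits of the respiratory chain and of ATP synthase. The log2 changes ran from -0.65 in ND4L, a subunit of complex I, to -0.35 in COX1, a subunit of cytochrome c oxidase, with a median of -0.43. ATP6, a subunit of ATP synthase, had 3773 ± 431 FPKM in normal gill and 2658 ± 208 under hypoxia, with the smallest p of the list (log2 -0.50, limma adjusted p = 0.11). ND6, of complex I, had 2883 ± 621 and 1899 ± 87.5 FPKM (log2 -0.58, limma adjusted p = 0.14). ND4L had 3484 ± 822 and 2193 ± 280 FPKM (limma adjusted p = 0.16).

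Adjusted over the list alone, 0 of the 11 genes passed either, with a smallest adjusted p of 0.055 by limma, while 5 had an unadjusted p under 0.05. Voom on the recovered reads, chosen after seeing the data, called 5 when adjusted over the list alone and 0 over all genes. The groups did not overlap in 6 of the 11, against 25.9% of all tested genes and 10% by chance, and the 11 genes are correlated and not independent draws. Camera with the preset correlation placed the list below the other genes (p = 3.1e-06). That call was lost with an estimated correlation of 0.72 between the genes (p = 0.16, but p = 0.047 without normal replicate 3), and fry, which does not compare the list with other genes, gave p = 0.063 for a shift in 1 direction and p = 0.051 for a change in either. In the oxidative phosphorylation list, with only COX1 and COX3 matched, COX3 passed when adjusted over the list alone (limma adjusted p = 0.045) and 0 passed over all genes. As a share of all reads, the 11 genes held 4.51 ± 0.90% in normal gill and 3.30 ± 0.21% under hypoxia (SD, n = 3 each; exact permutation p = 0.1, two-sided, the smallest possible). The normal libraries stood at 4.04, 3.95 and 5.55%, and the hypoxia libraries at 3.24, 3.54 and 3.13%. Without normal replicate 3 the median log2 change of the list was -0.21.

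**Figure D3:**
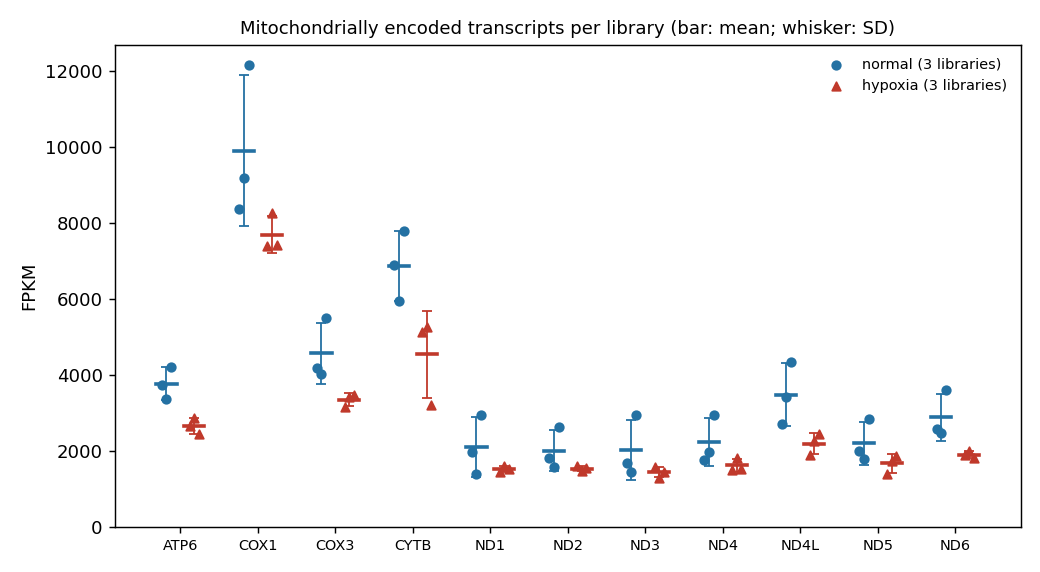
FPKM of the 11 mitochondrially encoded genes in each library on a linear axis from 0. Circles are the 3 normal and triangles the 3 hypoxia libraries, bars are means and whiskers SD. All 11 means are lower under hypoxia (COX1 turned to +0.15 under quantile normalization), from 3773 to 2658 FPKM for ATP6, and the groups stand apart in 6 of the 11.

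The breadth of expression was compared between the groups as well. Genes at FPKM of 1 or more numbered 13354 ± 465 in normal and 13507 ± 45.5 in hypoxia libraries (SD, n = 3 each; exact permutation p = 0.7, two-sided). The difference of 153 genes has no steady direction, at 402 without normal replicate 1, -58.8 without normal replicate 3 and -62.7 for genes above 0 FPKM. The 20 highest genes held 16.4 ± 1.16% of total FPKM in normal gill and 14.7 ± 0.84% under hypoxia (exact permutation p = 0.1, two-sided, the smallest possible with 3 against 3). For the 5 highest and the 100 highest genes the exact permutation p was 0.3. The mitochondrial genes, such as COX1 with means of 9908 FPKM in normal gill and 7693 under hypoxia, were not left out of these shares. The lower share may therefore not be separate from their lower values.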

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

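Voom on the recovered reads and the removal of the length trend were chosen after seeing the data. Under every alternative, all genes changed in the main test that were tested again kept their direction. For the left-out libraries, pseudocount and array weights this was fixed in advance, because the groups did not overlap in any of these genes. The filters, the variance models and the replicate block leave the change itself as it was, so its direction could not turn there either. Only library scaling, quantile normalization, voom and removal of the length trend could have turned a direction. Without a filter on low values 99 genes were higher and 27 lower, and with the replicate number as a replicate block 46 and 5. The block's added terms can lower the number of calls by themselves. The replicate numbers are not stated to mark pairs, and same-numbered libraries deviated together with correlations of 0.10, 0.01 and -0.09. These were not compared with differently numbered libraries, so a pairing is not excluded. Leaving out 1 library gave 38 to 172 genes higher and 8 to 43 lower, the fewest without hypoxia replicate 2 and the most without normal replicate 1. Fewer libraries enter those fits. The share of changed genes that were higher ran from 70.6 to 90.5% over all alternatives. Of the mitochondrial genes, adjusted over the list alone, limma called 2 with libraries rescaled to an equal sum, 4 at a mean FPKM of 5 or more, 3 under quantile normalization, 3 with array weights, 5 with voom, 3 with the length trend removed, and 0 to 1 with 1 library left out. The median log2 change of the list was -0.31 under quantile normalization, where COX1 reversed to 0.15 and the cause was not tested. It ran from -0.58 without normal replicate 2 to -0.21 without normal replicate 3. The camera call was lost at an estimated correlation (p = 0.16, and 0.047 without normal replicate 3), and fry, which compares the list with no change, gave p = 0.063. LOC110458710 passed in 11 of the 16 alternatives whose filter kept it (limma adjusted p from 0.0028 to 0.065) and missed under the replicate block, with voom and without each hypoxia library. The other alternatives left the counts of changed genes within 1.5 times the main ones. At this depth a gene with 0 reads is limited only to under 3 reads per library. The planned product families were not run, as the genes have no descriptions here.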

Other observations

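The tests of neighbouring genes, of genes without reads in one group, of the length trend, of read shares and of the splits for the count of changed genes were chosen after the data were seen. Leaving out each library was planned, but the reading of the mitochondrial genes without normal replicate 3 was chosen after their values were seen. Rising genes formed 12 runs of adjacent genes with 29 members, 9 runs of 2, 2 of 3 and 1 of 5. The single adjacent pair among the genes that fell was LOC110458707 and LOC110458710, named after their values were seen. LOC110458707 had 2752, 3131 and 639 reads in the normal libraries and 0 in each hypoxia library. Between them lies LOC110458708, which was too low to be tested and had FPKM of 2.51, 3.73 and 0.11 in normal and 0 in each hypoxia library.

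The adjacency of rising genes exceeded random placement of the calls. There were 17 adjacent pairs, against a mean of 2.58 and a maximum of 10 in 10000 shuffles (one-sided permutation p = 1e-04, the smallest they can give). Overlapping gene models that count the same reads do not account for it, since 15 pairs remained without overlapping spans, against a shuffled mean of 2.44. The pairs depend on the calls, with 1 pair when any hypoxia library was left out, 10, 7 and 5 without normal replicates 1, 2 and 3, 8 without a filter on low values, 10 at a mean FPKM of 5 or more and 4 under the replicate block, none of which was compared with shuffles. Reads shared between near-identical copies stay open, since no sequence was used here, and no biological explanation was tested.

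The lower values of the 11 mitochondrial genes have several candidate explanations. Removing each library's trend with length left their median log2 change at -0.41, and median ratio scaling left it at -0.48, against -0.43 in the main test. Rescaling the libraries to an equal sum left it at -0.35, and quantile normalization left it at -0.31 with COX1 reversed to 0.15. The size of the difference thus depends on the scaling. None of these settings removed it from the list's median. That argues against transcript length and against reads taken up by induced genes as the whole cause, and not against a part. The spread across the genes (SD 0.11) does not measure the spread between scallops. Camera with an estimated correlation gave p = 0.19 with the length trend removed and p = 0.21 with median ratio scaling. Without normal replicate 3 the median was -0.21 with all 11 genes still lower. Camera with an estimated correlation then gave p = 0.047, the only setting in which it fell under 0.05. The difference in read share went from -1.21 to -0.69 percentage points, with the other normal libraries (4.04 and 3.95%) above the hypoxia libraries (3.13 to 3.54%). In 1 of 10 splits, the real one, the mean change was as large in size (-0.47, highest other 0.35), and 10 splits are too few for a share under 0.05. That library thus widens the difference, and whether it is the whole of it stays open, since only 2 normal libraries remain without it.

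Patterns of complete absence were also counted. At FPKM of 2 or more wherever present, 6 genes had reads in all normal and 0 in all hypoxia libraries, against 1 in the reverse pattern and at most 2 in any other set of 3 libraries. Low depth does not account for the 6, since their lowest normal count was 131 reads. Presence or absence of these genes between individual scallops, whatever the oxygen, cannot be told apart from an effect of hypoxia, because at FPKM of 1 or more the counts were 7 against 6. A further 46 genes were found in normal replicate 1 alone, with a median of 27 reads, against 3 or fewer in any other single library.

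The count of 262 changed genes was compared with other groupings. In 1 of the 10 splits of the 6 libraries, the real one, as many genes changed, and the highest other split gave 5. With 10 splits no share under 0.05 can be reached. Expression varied more between normal scallops, with a median SD per gene of 0.246 on the log2 scale against 0.189 under hypoxia, a difference that was not tested. Without 1 normal library the normal value was 0.188 to 0.218, and without 1 hypoxia library the hypoxia value was 0.148 to 0.158. Longer transcripts had slightly higher changes, with a median log2 change of -0.033 in the shortest 10% of genes and 0.16 in the longest 10%, and a Spearman rho of 0.14 across genes, which are not independent replicates.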
